A study of Homo sapiens with 108 samples.

How the data were processed

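Total RNA from 108 surgically resected oesophageal squamous cell carcinomas, held in a tumour bank, had been hybridized as biotin-labelled cRNA to Illumina bead arrays. Per the labels, RNA was isolated with the mirVana kit, and 500 ng of it was amplified with the TotalPrep kit. All 108 arrays form 1 group of tumours, and the labels give no normal tissue, outcome, stage or batch. No comparison between groups of patients could therefore be made, and every result describes how genes differ, or vary together, between tumours.

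The authors deposited bead signals exported with BeadStudio (version not stated) as intensity, neither background-subtracted nor scaled between arrays, for 47231 probes. They hold no detection p and no control probes. A second file of the authors holds log2 values that were quantile-normalized over all arrays. Each of its columns has a median of 6.591, and its ranks match the deposited intensity of the same array for 108 of 108 arrays.

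Main values were computed from the deposited intensity. Of the arrays, 2 carried no signal (their brightest probe lay under 10 times the array's median, and the brighter of them reached 109.3) and were left out. The 3121 probes missing on some arrays were left out, which kept 44110. Missing probes were shared by all 12 arrays of a run of consecutive sample numbers in 2 of the 9 such runs. These runs of 12 were therefore treated as blocks of arrays, although the labels name no block. A single pair of arrays was near-identical (Pearson r 0.993 over the probes above background, against 0.964 for the next pair). It was averaged and counted once, so that 105 tumours were analysed.

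Background was corrected with normexp (saddle-point fit, offset 50), and arrays were quantile-normalized and put on the log2 scale (limma 3.58.1 in R 4.3.3, with tables read by the package data.table, version 1.17.8). The planned detection p was not in the files. A probe was instead called above background at p 0.01 against the array's own background, taken from its mode and the mirrored lower tail, and neqc gave way to normexp because it needs control probes. Probes above background on at least 10% of arrays were kept (25749). Gene symbols were updated through Entrez identifiers with a RefSeq annotation of assembly GRCh38.p14, and cytobands are those of the array file. A gene's value is that of its probe with the highest mean signal, which gave 18304 genes. XIST, TSIX and Y-linked genes were removed before any test. No result sets the level of one gene against that of another, since probes bind with different strength.

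The first principal component of the 105 tumours held 16.8% of the variance and followed the array's share of probes above background (absolute r 0.870). Main values are therefore mostly also given for the 90 tumours kept by a quality rule, with values centred within blocks. That rule leaves out arrays whose median correlation with the others lies over 3 MAD below the median (under 0.86). Below, this second set of values is called block-centred, although it also leaves out the 15 arrays that fail the rule. A result held when it passed its test, with the same sign, in both.

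The following were fixed before the data were examined: 42 gene lists (792 members, 675 of them analysed), 40 pairs of lists, 25 pairs of genes, the tests, the rule for named genes and most of the alternatives below. Of the other members, 87 were not above background on 10% of arrays and 30 had no probe with a value on every array. No gene stands in more than 1 list. The use of blocks, the joint setting of quality rule and blocks, the handling of arrays without signal and of the near-identical pair, and the rule for separate clusters were chosen after seeing the data.

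A list's score is the mean over its members of each gene's z-score across tumours, scaled to an SD of 1. List spread is the median SD of its members, and list coherence is their mean pairwise Pearson r. Each was set against 10000 random lists of the same size, matched on mean signal in 20 bins. The spread test was two-sided and the coherence test one-sided. Pairs were tested with Pearson's r and Spearman's rho, each with a two-sided permutation test of 100000 resamples, whose smallest possible p is 1e-05. A pair is said to pass by the adjusted p of r unless rho is named. Intervals of r are 95% bootstrap intervals over 2000 resamples. The r was computed again without the 2 tumours farthest from the median of the first measure and within each block. A pair of genes got no pooled r where the density of either gene showed 2 peaks parted by a valley under 0.5 of the lower peak. It was then tested within each cluster, exactly where a cluster held fewer than 10 tumours. The 4 axis fits regressed each gene on a list score in SD units (limma, moderated with a trend), leaving out the members of that list. A gene passed at an adjusted p under 0.05 with a slope of at least 0.5 log2 per SD in size. All adjusted p are Benjamini-Hochberg values within a family. Named genes are, per list, the 4 members with the largest SD and the 2 most correlated with the rest of the list. Per fit they are the 10 steepest slopes in each direction among genes past the threshold. To these come the genes of the pairs, 16 preset genes and the 10 genes of largest SD. Other genes named below were chosen after their values were seen.

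The pipeline was tested on simulated data, random normal values with each gene's own mean and SD. Of 50 genes given each true slope of 0.6, 0.8, 1 or -0.8, 100% passed both thresholds, with mean fitted slopes of 0.599, 0.807, 1.003 and -0.819. None of 18091 genes without a slope did. Genes and score were drawn independently, without blocks or variation shared between genes, so this does not measure false calls from those. A true r of 0.4 was recovered as 0.409 on average over 200 pairs. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.

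Alternatives covered the authors' value table, quantile normalization without background correction, and no or a stricter detection filter (50% of arrays). They also covered the mean of a gene's probes, the quality rule, residuals on array signal and detection, another list score, scores held constant, and no minimum slope. Added later were centring within blocks, centring together with the quality rule, and keeping the 2 arrays without signal. For arrays, their number limits the precision, and signal over background limits what was measured at all.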

Results

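Expression of 18304 genes was analysed in 105 resected oesophageal squamous cell carcinomas, from 108 arrays in 1 group. The series title names small non-coding RNAs associated with recurrence, but the labels give no recurrence status, so no relation with recurrence could be computed. The questions below are which preset gene groups differed most between tumours, which varied together, and which genes rose or fell along 4 axes: squamous differentiation, proliferation, fibroblast content and T-cell content. The authors' deposited intensity had a median per array of 96.3 (5th to 95th percentile 79.5 to 117.1 over 106 arrays). The share of probes above background was 41.1% at the median and 17.2% at the 5th percentile. Since that share moved with the first principal component (absolute r 0.870), most main values are given beside block-centred ones from the 90 tumours that passed the quality rule. That rule did not end the dependence, since among these 90 the share still moved with the first component (absolute r 0.759).

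The 10 genes that differed most between tumours included several of keratinocytes. KRT13, a keratin of the non-cornified oesophageal lining, had a between-tumour SD of 2.84 log2 units, and its 95th percentile lay 247-fold above its 5th (n = 105, 244-fold with the 15 doubtful arrays left out). SPRR3, a precursor of the cornified envelope, had an SD of 2.79 and a 224-fold range. The elastase inhibitor PI3 (SD 2.59), the antimicrobial S100A7 (2.38), the keratinocyte gene KRTDAP (2.37), the stress keratin KRT6C (2.33) and the simple-epithelial keratin KRT19 (2.33) followed. CES1, a carboxylesterase, had an SD of 2.48, the cancer-testis gene GAGE2B 2.31, and IGLL1, an immunoglobulin light-chain-like gene, a 124-fold range. Of these 10 genes, 8 were also among the 10 most variable without the doubtful arrays. KRT6C, GAGE2B and IGLL1 have close relatives whose RNA the same probes can bind, and ranges are bounded below by background where a gene was not detected, since GAGE2B was above background in only 41.9% of arrays and SPRR3 in 74.3%.

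By list, stress keratins, squamous differentiation and matrix genes had the widest spread. The stress keratin list also holds S100A7, S100A8, S100A9, SERPINB3, SERPINB4, PI3 and SLPI, which are not keratins. Here and below, stress keratins stands for this whole list. The median SD of the stress keratin list was 1.73 against 0.78 in matched random lists (n = 105; 1.59 against 0.46 block-centred). It was 1.36 against 0.68 for squamous differentiation (1.199 against 0.45), 1.31 against 0.69 for matrix metalloproteinases (1.203 against 0.47) and 1.31 against 0.73 for fibroblast and collagen matrix genes (1.13 against 0.47). Of the metalloproteinase list the matrix-degrading MMP10 (SD 1.88), MMP1 (1.86) and MMP3 (1.78) spread most, and of the fibroblast list the collagen COL11A1 (1.59). The metalloproteinase list, here and below, also holds the inhibitor genes TIMP1, TIMP2 and TIMP3. Interferon response genes followed with a median SD of 1.21 (1.10 block-centred), 11q13.3 genes with 1.18 (1.05), basal keratinocyte genes with 1.16 (0.94) and then NRF2 targets (1.11). In the NRF2 list the aldo-keto reductases AKR1B10 and AKR1C2 had a 129-fold and a 108-fold range, and ALDH3A1, an aldehyde dehydrogenase, a 90.6-fold range.

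In all, 21 of 42 lists were more variable than random lists at an adjusted p of 0.05 (29 block-centred), and none was less variable. The other 13 of the 21, with median SDs from 0.59 to 1.02 (0.53 to 0.88 block-centred), were immediate early, mesenchymal transition, neutrophil chemokine and inflammation, hypoxia response, smooth muscle, MHC class I, T-cell attracting chemokine, macrophage, cancer-testis antigen, MHC class II, erythroid, immune checkpoint and cytotoxic lymphocyte genes. Block-centred, S-phase replication, skeletal muscle, endothelial, T cell, mast cell, columnar and glandular epithelium, Schwann and neural, and PIWI pathway genes also passed. Ribosomal protein genes (adjusted p = 0.0468) and snoRNP core and assembly protein genes (adjusted p = 0.0474) were then less variable than random lists. The remaining 11 lists passed in neither set.

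Members of most lists rose and fell together. Fibroblast and collagen matrix genes had a mean pairwise r of 0.64 (0.70 block-centred), with the collagen COL1A2 at r 0.94 and the proteoglycan VCAN at r 0.93 to the rest of the list. Interferon response genes reached 0.61 (0.68), led by the antiviral IFIT3 and IFIT1. MHC class II genes reached 0.57 (0.66), led by HLA-DRA and HLA-DPA1, and smooth muscle genes 0.56 (0.65), led by DES and CNN1, parts of the contractile apparatus. Squamous differentiation genes reached 0.52 (0.52), led by the kallikrein KLK13 and the envelope gene CNFN. The redox-related NRF2 targets reached 0.48 (0.56), led by SRXN1 and NQO1.

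Among epithelial, proliferation and chromosome lists, mean pairwise r was 0.50 for stress keratins (0.51 block-centred), 0.41 for G2/M proliferation (0.44, led by TOP2A, a topoisomerase of dividing cells), 0.40 for basal keratinocyte (0.37), 0.40 for 11q13.3 (0.44), 0.32 for S-phase replication (0.30) and 0.22 for 3q26-q28 genes (0.28). Among other cell types and immune lists it was 0.50 for MHC class I (0.56), 0.41 for cytotoxic lymphocyte (0.53), 0.40 for macrophage (0.49), 0.39 for B and plasma cell (0.37), 0.36 for erythroid (0.41), 0.35 for endothelial (0.45), 0.33 for mast cell (0.47) and 0.31 for neutrophil chemokine genes (0.28). It was 0.27 for T cell (0.31), 0.21 for T-cell attracting chemokine (0.33), 0.15 for immune checkpoint (0.25), 0.10 for neutrophil (0.115), 0.075 for Schwann and neural (0.065) and 0.065 for columnar and glandular epithelium genes (0.069). For the remaining lists that passed it was 0.33 for matrix metalloproteinase (0.33), 0.28 for mesenchymal transition (0.32), 0.27 for glycolysis (0.19), 0.26 for hypoxia response (0.29), 0.25 for immediate early (0.27), 0.24 for cholesterol synthesis (0.25) and 0.23 for cancer-testis antigen genes (0.25). It fell furthest block-centred for oxidative phosphorylation (0.39 to 0.19), ribosomal protein (0.29 to 0.19) and snoRNP genes (0.22 to 0.093), which still passed.

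Thus 36 of 42 lists were more coherent than random lists at an adjusted p of 0.05 (40 block-centred). Heat shock (0.24, adjusted p = 0.0644), unfolded protein response (0.20, adjusted p = 0.0580), microRNA pathway (0.088, adjusted p = 0.0963) and snoRNA host transcript genes (0.043, adjusted p = 0.184) passed only block-centred. Skeletal muscle (0.025, adjusted p = 0.433) and PIWI pathway genes (0.038, adjusted p = 0.0580) passed in neither. Genes within a list are not independent replicates, and these values describe the arrays.

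**Figure D1:**
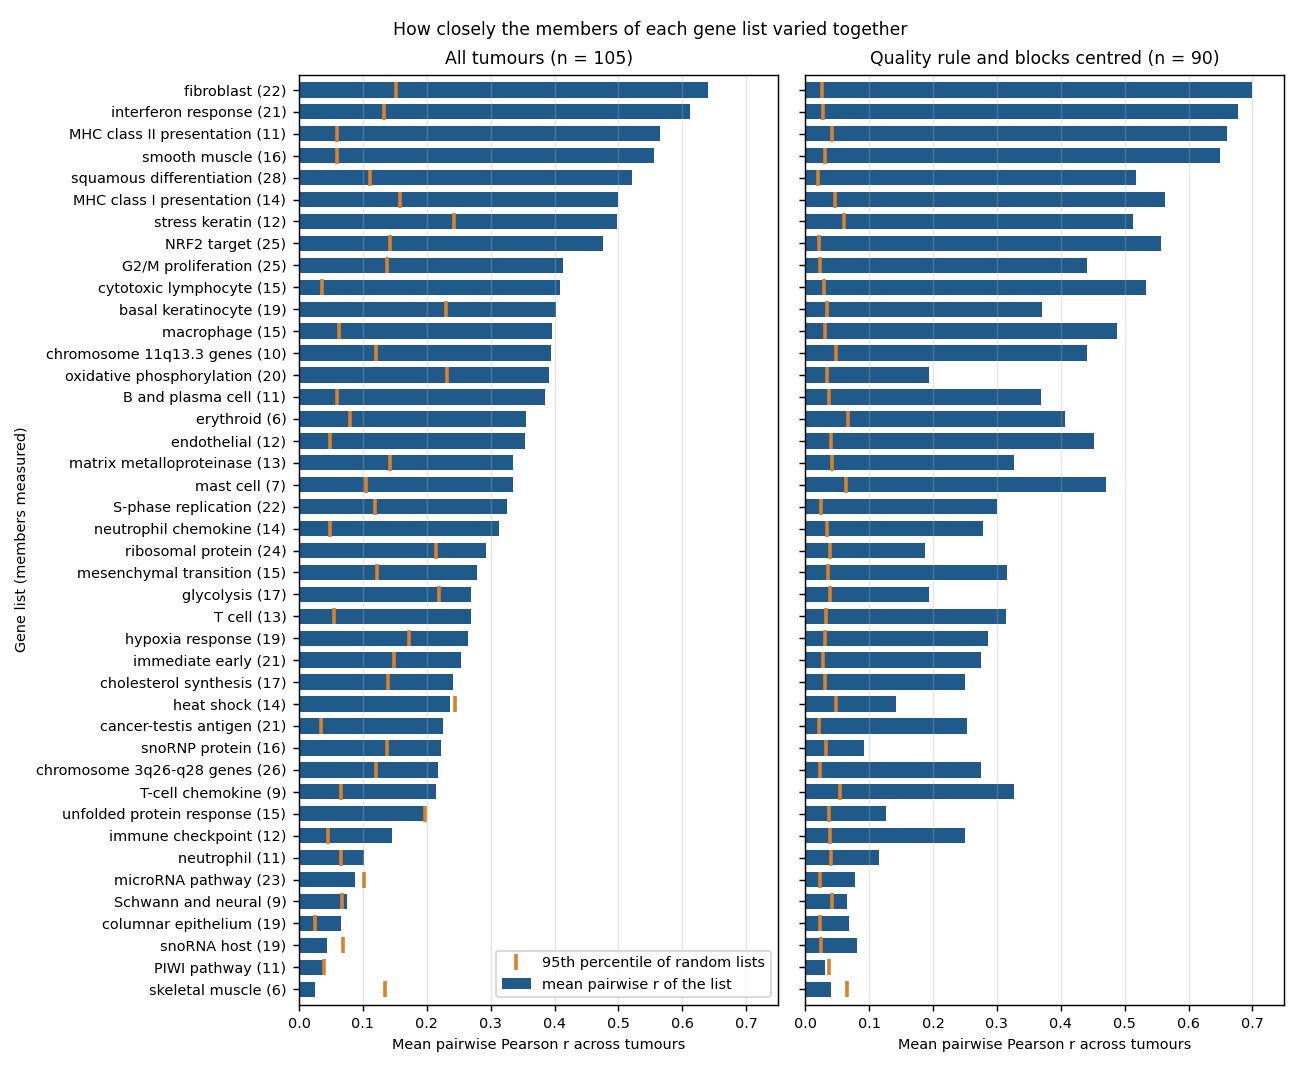
Mean pairwise Pearson r among the measured members of each of the 42 lists (bars; number of members in brackets) across 105 tumours (left) and block-centred in 90 tumours (right), with the 95th percentile of matched random lists (orange ticks). Fibroblast genes have the highest value (0.64 and 0.70), and the ticks move towards 0 in the right panel.

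Tumours with higher squamous differentiation scores had lower scores of fibroblast and of cell-cycle genes. The correlation of squamous differentiation with the fibroblast list was r = -0.41 (95% interval -0.56 to -0.23, permutation p = 3e-05, adjusted p = 6e-05, n = 105). The smallest p the permutations can give is 1e-05. Spearman's rho was -0.38 (p = 7e-05), r without the 2 farthest tumours was -0.36, and the sign held in 8 of 9 blocks. With G2/M proliferation the r was -0.40 (p = 6e-05, adjusted p = 0.000109, rho = -0.28 with p = 0.00391). It was -0.32 without the 2 farthest tumours, and the sign held in 6 of 9 blocks. Block-centred, these relations had r = -0.40 and -0.41. Differentiation rose with genes of the stress keratin list such as KRT6B (r = 0.67, 0.69 block-centred). It rose less closely with basal keratinocyte genes such as KRT5 and KRT14 (r = 0.37, 0.41 block-centred).

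Proliferation genes of different phases and of ribosome production went together. G2/M and S-phase replication scores had r = 0.87 (p = 1e-05, rho = 0.80 with p = 1e-05, r = 0.84 without the 2 farthest tumours, n = 105), positive in 9 of 9 blocks, and 0.78 block-centred. G2/M proliferation also rose with the core and assembly proteins of snoRNPs, which modify RNA (r = 0.67, 0.43 block-centred) and with 3q26-q28 genes (r = 0.49, 0.27 block-centred). snoRNP proteins rose with ribosomal proteins (r = 0.84, 0.66 block-centred), as did snoRNA host transcripts (r = 0.47, 0.35 block-centred). The permutations set these r against 0, and no random pairs of lists were drawn. Random lists matched to the G2/M and ribosomal lists had a median pairwise r of 0.072 and 0.122 (0.0009 and 0.0039 block-centred). An all-tumour r can thus come partly from variation shared across lists. The lowest r under any alternative was 0.339 for G2/M with snoRNP proteins and 0.389 for snoRNP with ribosomal proteins. Hypoxia response genes rose with glycolysis (r = 0.74, 0.65 block-centred) and mesenchymal transition genes (r = 0.46, 0.35 block-centred), and basal keratinocyte with mesenchymal transition genes (r = 0.36, 0.35 block-centred).

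Stromal lists moved together, and so did immune lists. The fibroblast score rose with matrix metalloproteinases (r = 0.83, p = 1e-05, rho = 0.81 with p = 1e-05, r = 0.82 without the 2 farthest tumours, n = 105, positive in 9 of 9 blocks, 0.80 block-centred) and with mesenchymal transition genes (r = 0.83, 0.81 block-centred). It rose less closely with macrophage (r = 0.43, 0.48 block-centred), smooth muscle (r = 0.38, 0.32 block-centred) and endothelial genes (r = 0.36, 0.35 block-centred). By rho, smooth muscle came first of these lists (0.665, 0.51 block-centred). For macrophage genes rho was 0.43 (0.45 block-centred) and for endothelial genes 0.45 (0.40 block-centred). T-cell genes such as CD3D rose with cytotoxic lymphocyte genes such as GZMA and NKG7 (r = 0.87, p = 1e-05, rho = 0.84 with p = 1e-05, r = 0.84 without the 2 farthest tumours, positive in 9 of 9 blocks, 0.88 block-centred). They also rose with B and plasma cell (r = 0.76, 0.68 block-centred), T-cell attracting chemokine (r = 0.75, 0.77), immune checkpoint (r = 0.74, 0.76) and MHC class II genes (r = 0.66, 0.69). Of the checkpoint list, CD274, PDCD1 and PDCD1LG2 were not above background on 10% of arrays, so its score does not cover them. Interferon response genes rose with MHC class I (r = 0.69, 0.71) and cytotoxic lymphocyte genes (r = 0.48, 0.49), and neutrophil genes with neutrophil chemokines such as CXCL8 (r = 0.51, 0.60).

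Of the 40 list pairs computed, 31 passed at an adjusted p of 0.05 over all tumours (27 positive and 4 negative), and 25 of them held block-centred (23 positive and 2 negative). All 25 kept their sign without the 2 farthest tumours, 19 had the same sign in 9 of 9 blocks and none in fewer than 6. Lost block-centred by r were differentiation with mesenchymal transition (r = -0.25 to -0.20), G2/M with T cell (-0.33 to -0.035), NRF2 target with glycolysis (0.29 to 0.15) and snoRNP protein with snoRNA host transcript (0.40 to 0.20). The last of these pairs still passed block-centred by rho (0.2255, adjusted permutation p = 0.0482). The microRNA pathway lost its relations with G2/M (0.23 to -0.14) and snoRNP proteins (0.34 to -0.17), and the latter rested on the 2 farthest tumours, with r = 0.093 without them. With the quality rule alone these microRNA pathway r were -0.137 and -0.153. With blocks centred over all tumours they were 0.245 and 0.385, and that of G2/M with T cell was -0.321. By r, basal keratinocyte genes fell with G2/M proliferation (r = 0.068 over all tumours, -0.28 block-centred) and with 3q26-q28 genes (-0.078 and -0.37) only block-centred. By rho, the relation with 3q26-q28 genes also passed over all tumours (-0.23, adjusted permutation p = 0.0220).

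Another 7 pairs passed in neither set. Differentiation had r = 0.0079 with columnar and 0.043 with NRF2 target genes, and G2/M proliferation had r = 0.091 with 11q13.3 genes. Smooth muscle had r = 0.15 with skeletal muscle and -0.036 with immediate early genes, and T-cell genes had r = -0.089 with fibroblast and -0.063 with cancer-testis antigen genes.

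**Figure D2:**
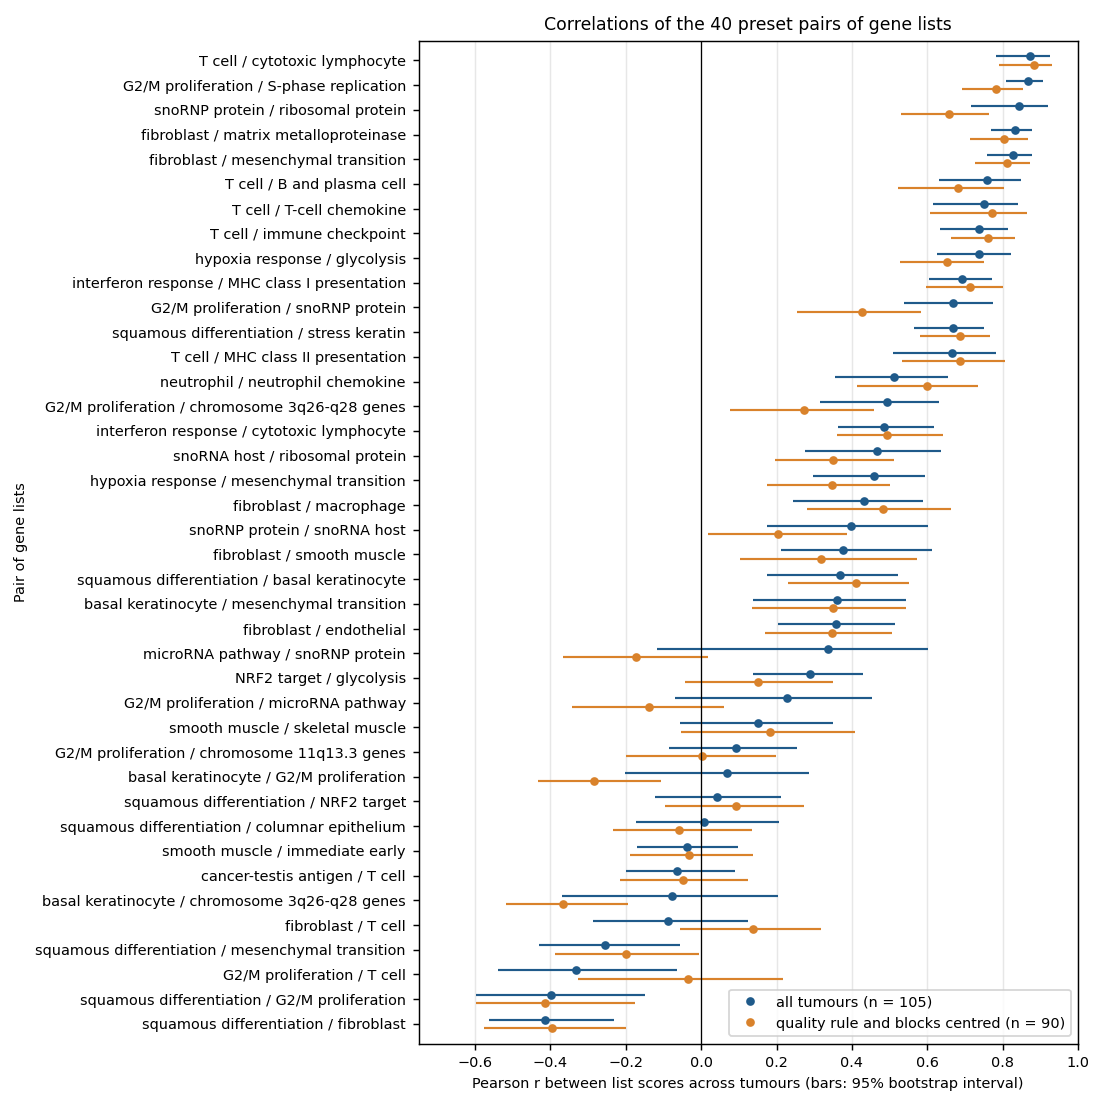
Pearson r between the scores of the 40 preset list pairs (points) with 95% bootstrap intervals (bars), over 105 tumours (blue) and block-centred in 90 tumours (orange). T-cell and cytotoxic genes are at the top (0.87 and 0.88), and differentiation with fibroblast genes at the bottom (-0.41 and -0.40).

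**Figure D3:**
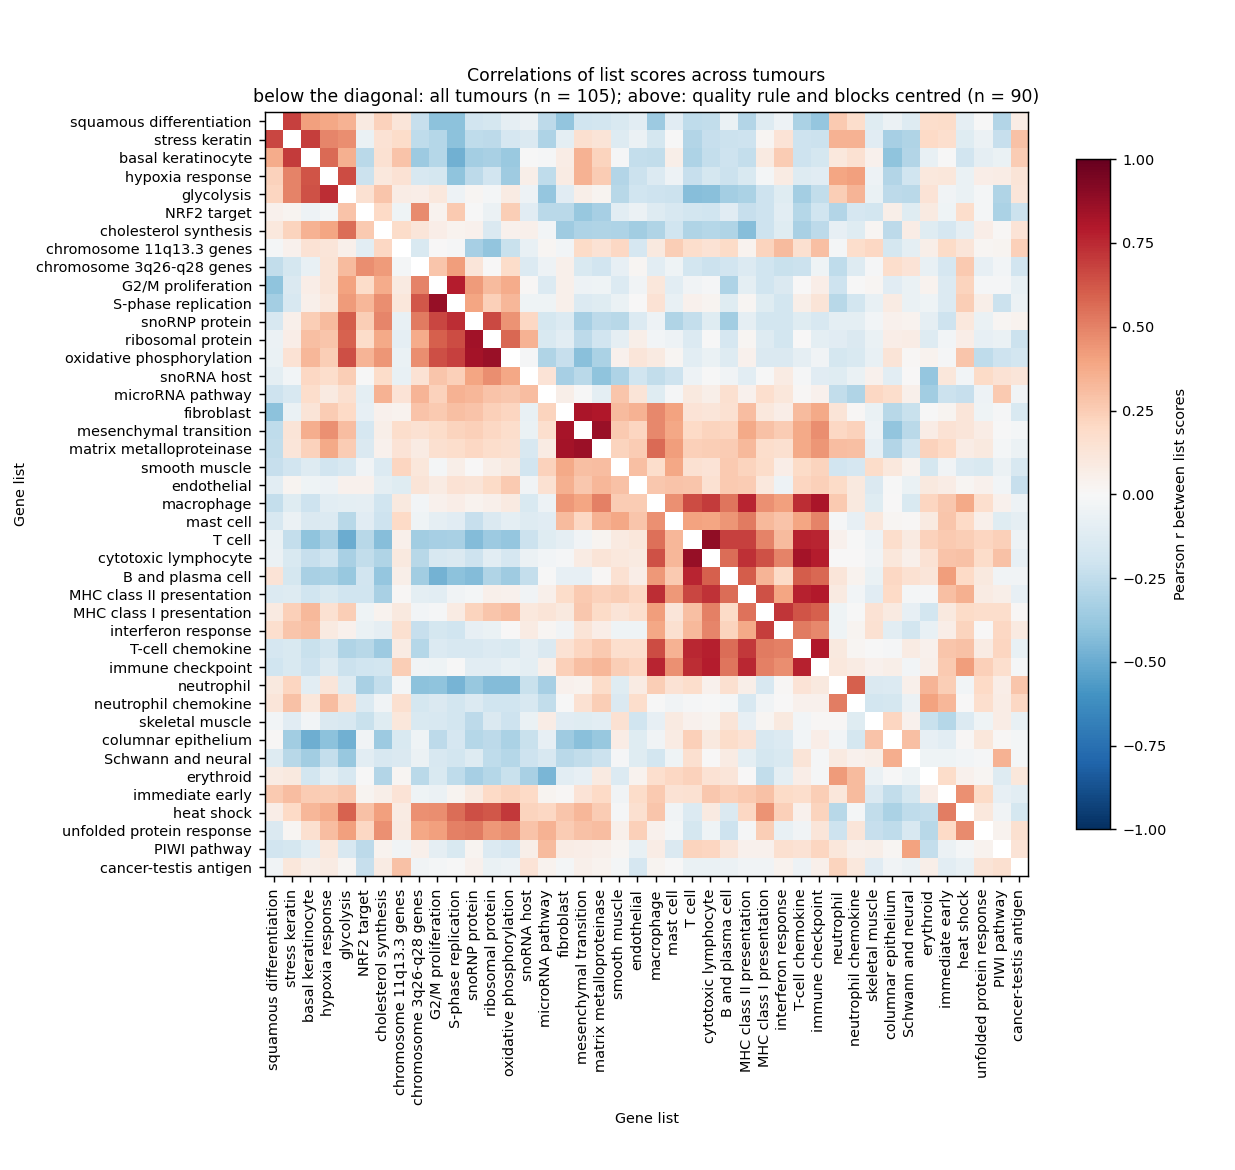
Pearson r between the scores of all 42 lists, over 105 tumours (below the diagonal) and block-centred in 90 tumours (above it), red for positive and blue for negative. Immune lists such as T cell and cytotoxic lymphocyte (0.87 below, 0.88 above) form 1 red square.

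Neighbouring genes of 11q13.3 varied closely together. FADD, an adaptor of death receptors, and PPFIA1, a scaffold protein, had r = 0.77 (p = 1e-05, adjusted p = 3.75e-05, rho = 0.76 with p = 1e-05, r = 0.75 without the 2 farthest tumours, n = 105, positive in 9 of 9 blocks, 0.84 block-centred). CCND1, the cyclin D1 gene, had r = 0.52 with FADD (0.75 block-centred) and 0.51 with CTTN (0.60), the cortactin gene. CTTN had r = 0.51 with the chloride channel gene ANO1 (0.62 block-centred). CCND1 itself had a 17.9-fold range between the 5th and 95th percentile, and ANO1 a 38.4-fold range.

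Of the other preset gene pairs, TP63, a transcription factor of basal squamous cells, rose with KRT5 (r = 0.47, 0.60 block-centred, but 0.26 without the 2 farthest tumours and rho = 0.25). ERBB2 and its neighbour GRB7 had r = 0.36 with a bootstrap interval that includes 0 (-0.038 to 0.682), and 0.62 block-centred (0.376 to 0.770). MYC rose with PVT1 (r = 0.38, 0.30), CDKN2A with MTAP (r = 0.295, 0.25) and AGO2 with PTK2 (r = 0.27, 0.42). CDKN2A parted into 2 clusters only with the doubtful arrays left out, so that its second r pools them. The microRNA processing enzymes DROSHA and DICER1 had r = 0.22 (adjusted p = 0.0368), which was lost block-centred (0.094). EGFR and its neighbour SEC61G had r = 0.051 over all tumours and by r passed only block-centred (0.51). Their rho passed over all tumours too (0.27, adjusted permutation p = 0.0119). With blocks centred over all tumours their r was 0.10. By r, KRT13 with MKI67, CDKN2A with RB1, DICER1 with MKI67 and SOX2 with TP63 passed in neither set (r from -0.18 to -0.071). By rho, CDKN2A with RB1 passed over all tumours (-0.27, adjusted permutation p = 0.0119) but not block-centred (-0.10).

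Pooled r was computed for 15 of the 25 preset gene pairs, of which 10 passed and 9 held. All 9 kept their sign without the 2 farthest tumours, and the sign held in at least 7 of 9 blocks. In 4 pairs a gene fell into separate clusters. KRT4 and KRT13 had r = 0.49 in the 92 tumours of the lower KRT4 cluster (permutation p = 1e-05) and 0.44 in the 13 others (p = 0.123). KRT13 and CRNN, a late differentiation gene, had r = 0.45 in the 86 tumours with low CRNN (p = 1e-05) and 0.53 in the 19 others (p = 0.0195). CRNN was above background in only 42.9% of arrays, so many values in its lower cluster are bounded by background. PIK3CA and ACTL6A of 3q26 had r = 0.60 in 98 tumours (p = 1e-05) and -0.10 in the other 7 (exact permutation p = 0.847), all 7 of which failed the quality rule. GAS5 and FBL had r = 0.048 in 98 tumours (p = 0.636) and -0.38 in the other 7 (exact permutation p = 0.2998), of which 4 failed the quality rule. Without the arrays of that rule neither ACTL6A nor GAS5 parted into clusters. The remaining 6 pairs had a gene that was not analysed. CD274, ZEB1 and FGFR1 were not above background on 10% of arrays, and AKR1C3 had no probe with a value on every array.

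**Figure D4:**
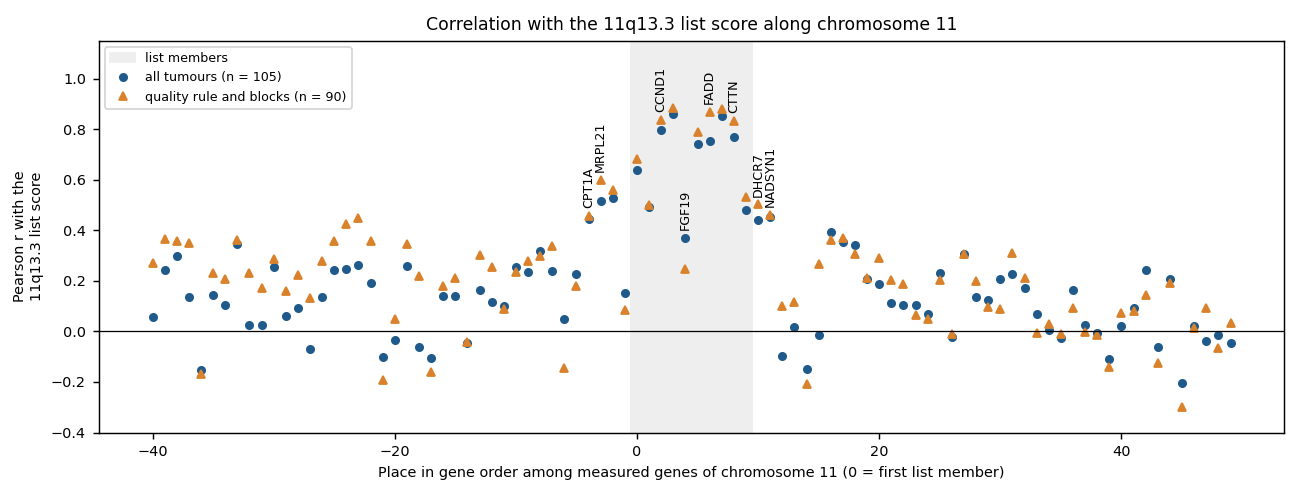
Pearson r of each measured gene with the 11q13.3 list score, by place in gene order on chromosome 11 (0 is the first list member), over 105 tumours (blue) and block-centred in 90 tumours (orange). List members (grey band) include CCND1 at 0.79 and LTO1 at 0.86, which count in the score themselves, and neighbours outside the list such as MRPL21 reach 0.51.

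Along the squamous differentiation score, SPRR2 and other keratinocyte genes rose and several collagen genes fell. SPRR2F rose by 1.68 log2 per SD of the score (SE 0.13, n = 105, adjusted p = 6.71e-20), SPRR2E by 1.63 (SE 0.15) and SBSN, a gene of suprabasal keratinocytes, by 1.55 (SE 0.14). PI3 rose by 1.36 (SE 0.21), LCN2, an iron-binding defence protein, by 1.32 (SE 0.15) and CYSRT1 by 1.40 (SE 0.07). SPRR2D, SPRR2C, NCCRP1 and the uncharacterised LOC641835 also rose, and SPRR2 probes can bind RNA of several SPRR2 genes. CTHRC1, a matrix-secreted collagen-related gene, fell by 0.69 (SE 0.12, adjusted p = 4.02e-06), the proteoglycan VCAN by 0.68 (SE 0.13) and COL1A2 by 0.68 (SE 0.14).

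In this fit 158 of 18276 genes were higher and 16 lower, against 134 and 4 block-centred, and 121 and 4 passed in both. The 4 lower in both were CTHRC1, VCAN, COL1A2 and COL3A1. With the fibroblast, proliferation and T-cell scores in the model, limma called 0 genes lower with the minimum slope. Without that minimum, 1487 were lower at an adjusted p under 0.05 (2707 at an unadjusted p of 0.05). These 4 count in the fibroblast score themselves, so that the shrinking of their slopes (to between -0.20 and 0.089) follows largely by construction. COL11A1, COL5A2, CDH11, COL8A1, ACTG2 and MMP11 had block-centred slopes under the minimum, from -0.50 to -0.23. Of 12 stress keratin genes 10 were higher (9 block-centred, and 12 at an adjusted p alone, adjusted over the list alone). Of 19 basal keratinocyte genes 4 were higher (3 block-centred, and 12 adjusted over the list alone), and 2 hypoxia response, 1 neutrophil, 1 neutrophil chemokine, 1 interferon response and 1 heat shock gene (1, 1, 1, 0 and 1 block-centred). Block-centred, 2 NRF2 target genes and 1 immediate early gene were higher too. Of 22 fibroblast genes 9 were lower (4 block-centred, and 21 adjusted over the list alone), and 1 mesenchymal transition, 1 metalloproteinase and 1 smooth muscle gene (0 of each list block-centred). No G2/M gene reached the minimum slope, and 20 of 25 were lower adjusted over the list alone.

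Along the fibroblast score, matrix-remodelling genes rose and several late differentiation genes fell. The metalloproteinase MMP11 rose by 1.33 log2 per SD (SE 0.09, n = 105, adjusted p = 2.33e-26, 1.13 block-centred), the collagen-degrading protease CTSK by 1.29 (SE 0.06, 1.09 block-centred) and SFRP2, a secreted modulator of Wnt signals, by 1.19 (SE 0.07, 1.07 block-centred). TIMP2, an inhibitor of metalloproteinases, COL8A1, ISLR, AEBP1, CDH11, the smooth muscle actin ACTG2 and the growth factor CCN2 rose by 1.02 to 1.12. TGM3, an envelope cross-linking enzyme, fell by 0.89 (SE 0.18, -0.80 block-centred), MAL by 0.87 (SE 0.19), CRNN by 0.85 (SE 0.19) and KRT4 by 0.84 (SE 0.17). SPRR3, S100P, CEACAM6, CYSRT1, KLK12 and SPRR1B fell by less.

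Here 138 of 18282 genes were higher and 38 lower (95 and 30 block-centred, 89 and 22 in both). With the differentiation, proliferation and T-cell scores in the model 162 were higher and 3 lower, and none of the 10 lower genes named above passed. For TGM3, MAL, CRNN, KRT4, SPRR3 and SPRR1B this follows largely by construction, as they count in the differentiation score, while S100P, CEACAM6, CYSRT1 and KLK12 do not. Higher were 6 of 15 mesenchymal transition genes, 5 of 13 genes of the metalloproteinase list (TIMP2 among them) and 5 of 16 smooth muscle genes. Block-centred these counts were 5, 5 and 4, and adjusted over the list alone 14, 12 and 10. Of 28 squamous differentiation genes 14 were lower (11 block-centred, and 23 adjusted over the list alone). Also higher were 2 basal keratinocyte, 1 macrophage, 1 hypoxia response and 1 immediate early gene (0, 2, 0 and 1 block-centred), and 1 snoRNA host transcript was lower (0 block-centred). Block-centred, 3 NRF2 target genes and 1 columnar epithelium gene were lower too. Without background correction 79 genes were higher and 21 lower.

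Along the T-cell score, the steepest genes included probes of immunoglobulin genes, for which no list was preset, and 3 MHC class II genes. IGLL1 rose by 0.99 log2 per SD (SE 0.20, n = 105, adjusted p = 0.000136, 1.29 block-centred), and 5 probes described in the array file as immunoglobulin kappa or gamma chain genes by 0.78 to 0.97 (LOC642113, LOC652694, LOC652493, LOC649923 and LOC647450). HLA-DMB, HLA-DMA and HLA-DRA, which present peptides or load them, rose by 0.90 (SE 0.09), 0.83 (SE 0.09) and 0.77 (SE 0.12). LOC647506, with no function in the file, rose by 0.93. ODC1, the first enzyme of polyamine synthesis, fell by 0.76 (SE 0.13), the NRF2 target AKR1C2 by 0.72 (SE 0.20, -0.77 block-centred) and the hyaluronan synthase HAS3 by 0.71 (SE 0.13, -0.61 block-centred). SERPINB5, IGFBP2, AKR1B10, PI3, KRT17P3, FABP5P9 and LOC650517 also fell, and 4 of the 10 did not pass block-centred. Of these ODC1, SERPINB5 and IGFBP2 had slopes just under the minimum in size (-0.48 to -0.46), and PI3 a slope of -0.72 with an adjusted p of 0.0607.

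In this fit 56 of 18291 genes were higher and 34 lower (66 and 23 block-centred, 46 and 15 in both). Lower genes numbered 13 with the other 3 scores in the model and 8 with the first component as list score, and none of the 10 lower genes named above passed under every alternative run, while the 10 higher ones did. Higher were 5 of 11 MHC class II, 4 of 15 cytotoxic lymphocyte, 3 of 15 macrophage, 3 of 12 immune checkpoint, 3 of 9 T-cell attracting chemokine and 2 of 11 B and plasma cell genes. Block-centred these counts were 5, 7, 3, 3, 3 and 2, and adjusted over the list alone 11, 15, 14, 8, 8 and 11. Lower were 4 of 25 NRF2 target genes (3 block-centred, and 14 adjusted over the list alone), 2 of 12 stress keratin (3 block-centred) and 2 of 19 basal keratinocyte genes (1 block-centred), and 1 of 21 interferon response genes was higher (0 block-centred). Block-centred, 2 squamous differentiation genes were lower, and 1 metalloproteinase and 1 MHC class I gene higher. With the authors' log2 values 32 genes were higher, and without background correction 25 were higher and 21 lower.

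Along the G2/M proliferation score, replication genes rose over all tumours, with smaller slopes once doubtful arrays were left out. The score was scaled to an SD of 1 anew in each set, so the slopes are not in the same unit. The median SD of the G2/M list itself was 0.72 over all tumours and 0.54 block-centred. MCM2, a subunit of the replicative helicase, rose by 0.72 log2 per SD (SE 0.06, n = 105, adjusted p = 2.22e-18, 0.41 block-centred), the replication clamp PCNA by 0.77 (SE 0.07, 0.32 block-centred) and PRC1, a gene of the mitotic spindle, by 0.76 (SE 0.05, 0.35 block-centred). UHRF1, RFC4, MCM4, CKAP5, the transferrin receptor TFRC, LAPTM4B and the epithelial adhesion gene EPCAM rose by 0.69 to 0.94. The differentiation genes MAL and CRNN fell by 0.82 (SE 0.19) and 0.74 (SE 0.19), but did not pass block-centred (adjusted p = 0.0905 and 0.1016), and with the other 3 scores in the model, in 1 of which they count themselves, their slopes turned to 0.049 and 0.136. Also lower were CLCA4, CEACAM6, KRT4, PLEKHN1, TNFSF15, NCCRP1, PHAX and CNFN, by 0.66 to 0.70. Of these, CLCA4, CEACAM6, CNFN, NCCRP1 and KRT4 passed block-centred. With the other 3 scores in the model CEACAM6 and NCCRP1, which count in none of them, did not pass.

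In this fit 171 of 18279 genes were higher and 172 lower, but block-centred limma called 0 and 15, with 0 and 11 in both. At an adjusted p alone 701 genes were higher and 431 lower block-centred, and at an unadjusted p of 0.05 there were 1966 higher, none with a slope of 0.5. Without background correction 35 genes were higher and 66 lower, and with the authors' log2 values 72 and 99, so that the counts and their balance hang on the scaling. Of 22 S-phase genes 10 were higher (0 block-centred, and 20 adjusted over the list alone), and 19 had a higher slope at an adjusted p alone block-centred. Of 28 squamous differentiation genes 12 were lower (5 block-centred, and 20 adjusted over the list alone). Also higher were 3 fibroblast, 2 of 26 3q26-q28, 2 NRF2 target, 1 glycolysis and 1 oxidative phosphorylation gene and 1 snoRNA host transcript, and 1 snoRNA host transcript and 1 PIWI pathway gene were lower; none of these passed block-centred.

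**Figure D5:**
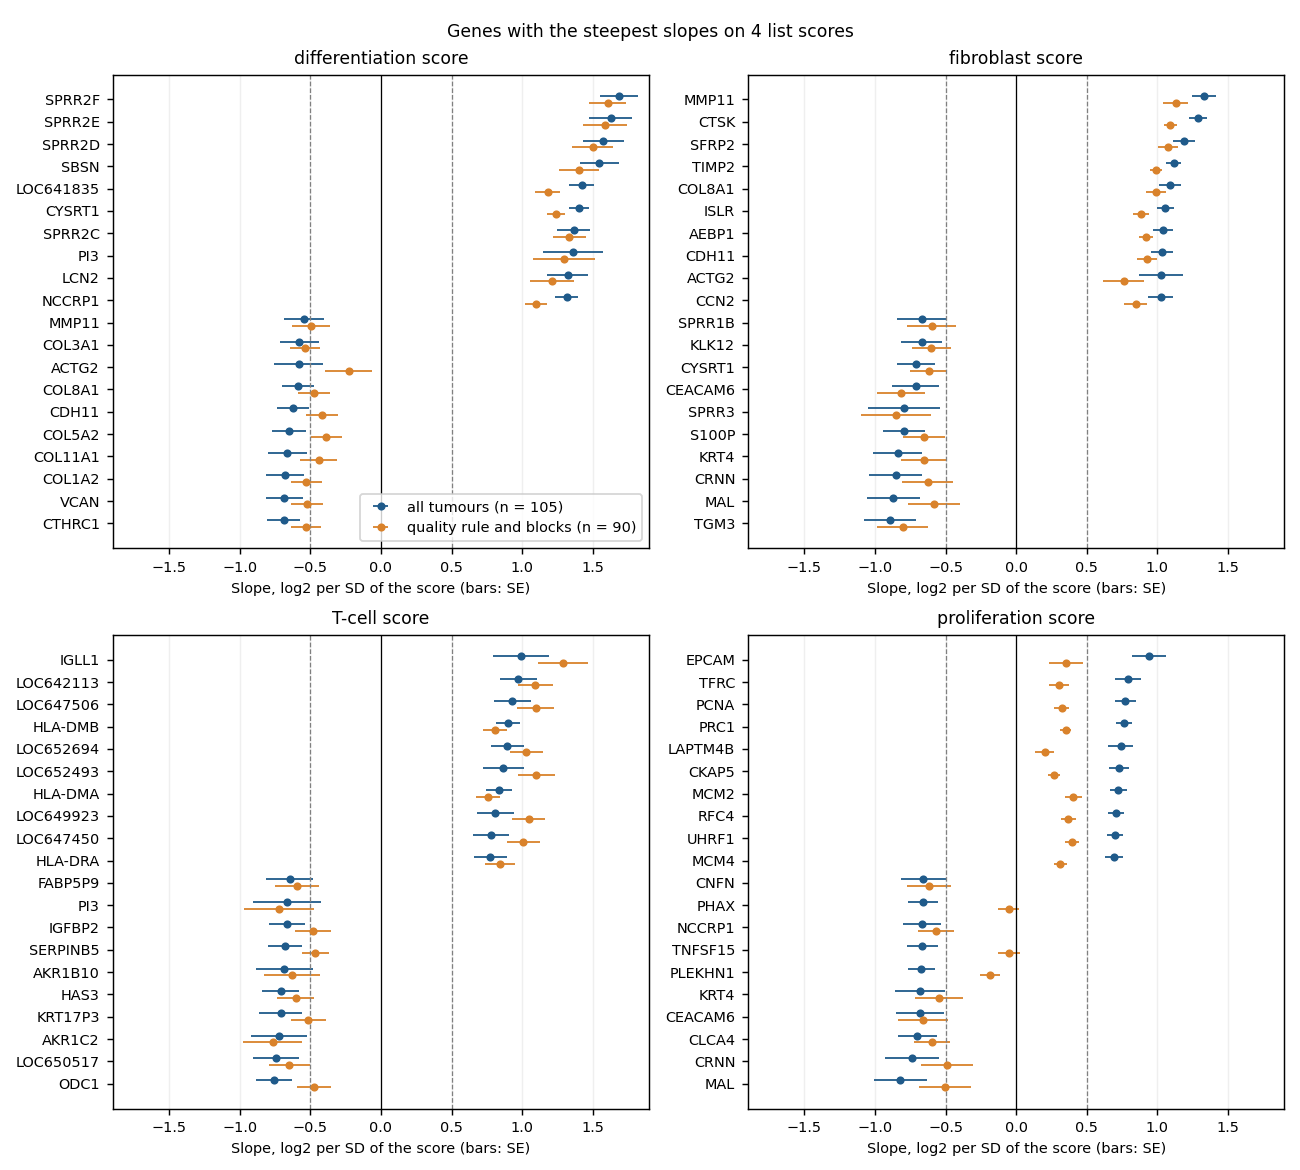
Slopes (points, log2 per SD of the score) with standard errors (bars) of the 10 steepest genes in each direction for each of 4 list scores, over 105 tumours (blue) and block-centred in 90 tumours (orange); dashed lines mark the minimum slope of 0.5. On the proliferation score the blue slopes of replication genes such as MCM2 (0.72) shrink to orange ones under 0.5 (0.41).

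Among the preset cancer genes, SOX2, a squamous lineage factor, and CCND1 differed most between tumours, with SDs of 1.34 and 1.32 (13.0-fold and 17.9-fold range, n = 105). The cell-cycle inhibitor gene CDKN2A had an SD of 1.16 and was above background in 33.3% of arrays. The redox regulator NFE2L2 had an SD of 1.08 and MYC 1.02, and these shrank to 0.76 and 0.79 without the doubtful arrays. ERBB2 (0.90), VEGFA (0.88), TP63 (0.83), EGFR (0.79), KEAP1 (0.75) and NOTCH1 (0.73) spread less. Of the microRNA pathway, DROSHA had an SD of 0.77, DICER1 0.64 and AGO2 0.61. CD274, the gene of the checkpoint ligand PD-L1, was not above background on 10% of arrays.

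Probes for microRNA genes were seldom above background. Of 835 probes named for small RNA genes, 250 were above background in at least 10% of arrays, or 29.9%, against 58.4% of all probes, a difference that was not tested. Without the MIR probes it was 178 of 308, or 57.8%. They were 62 of 95 SNORA and 80 of 166 SNORD probes, for the snoRNAs that guide pseudouridylation and methylation, 17 of 19 RNU, 11 of 19 SCARNA, 4 of 4 RNY, 3 of 3 RN7S, 1 of 2 VTRNA and 72 of 527 MIR probes. In at least 50% of arrays 128 were above background, and in every array 6. The labelling starts from polyadenylated RNA by its usual protocol, and whether these probes read mature small RNA, precursors or host transcripts was not tested.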

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

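Centring within blocks, centring together with the quality rule, and keeping the 2 arrays without signal were chosen after seeing the data, and the other alternatives before. Unless noted, the cause was not tested. Of the list pairs past the threshold, 25 of 31 kept their direction and their side of it under every alternative run, and of the gene pairs 9 of 10. T cell with cytotoxic lymphocyte ranged from r = 0.857 to 0.908, squamous differentiation with fibroblast genes from -0.444 to -0.332, and FADD with PPFIA1 from 0.764 to 0.836. Of the 20 genes named per fit, 10 kept it in the differentiation, fibroblast and T-cell fits and 0 in the proliferation fit. Values below follow in the order higher and lower genes, or as r.

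With the authors' log2 values the proliferation fit gave 72 and 99 and the T-cell fit 32 higher. Without background correction, proliferation gave 35 and 66, fibroblast 79 and 21, T-cell 25 and 21, and differentiation 8 lower. With no detection filter, smooth muscle with skeletal muscle had -0.0117 and cancer-testis antigen with T cell 0.00687; with detection in 50% of arrays, fibroblast with T cell had 0.0117 and the T-cell fit gave 15 lower. Small RNA probes numbered 835 with no filter and 128 with the strict one, by construction. With the mean of a gene's probes, differentiation with columnar epithelium had -0.0109, SOX2 with TP63 0.00672, and the T-cell fit gave 19 lower.

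With the quality rule, proliferation gave 0 and 18 by limma (774 higher at an adjusted p alone, 2052 at an unadjusted p of 0.05). The T-cell fit gave 18 lower, and 1 list had a smaller spread. Then differentiation with columnar epithelium had -0.0303, basal with G2/M -0.264, G2/M with 11q13.3 -0.00571, G2/M with microRNA pathway -0.137, microRNA pathway with snoRNP -0.153 and fibroblast with T cell 0.0988. With residuals on signal and detection, these were -0.0136 for differentiation with columnar epithelium, -0.0896 for basal with G2/M and 0.0552 for fibroblast with T cell, and the fits gave 8 lower for differentiation and 7 and 24 for proliferation.

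With the first component as list score, fibroblast with T cell had 0.0472, proliferation gave 264 higher and the T-cell fit 88 and 8. With the first component of all genes held constant, differentiation with columnar epithelium had -0.0246, basal with G2/M -0.263, G2/M with microRNA pathway -0.0252, microRNA pathway with snoRNP -0.021 and fibroblast with T cell 0.0793. With fibroblast and T-cell scores held constant, differentiation had 0.180 with mesenchymal transition, -0.142 with columnar epithelium and -0.0242 with NRF2 target, and basal with G2/M -0.105. With the other 3 axes in the model, lower genes numbered 0 for differentiation by limma, 3 for fibroblast and 13 for T cell. For differentiation 1487 were lower at an adjusted p alone (2707 at an unadjusted p of 0.05). The slope was 0.089 for COL3A1 on differentiation, 0.136 for CRNN and 0.049 for MAL on proliferation and 0.1004 for SPRR3 on fibroblast. These 4 genes count in a score of that model themselves, so their slopes shrink partly by construction. With no minimum slope, more genes passed by construction: 1032 and 866 for differentiation, 5034 and 3512 for proliferation, 2968 and 1886 for fibroblast, 2080 and 2874 for T cell.

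Centred within blocks, smooth muscle with immediate early had 0.00296, differentiation gave 4 lower and proliferation 101 and 103. With quality rule and blocks together, differentiation with columnar epithelium had -0.0583, basal with G2/M -0.284, G2/M with microRNA pathway -0.139, microRNA pathway with snoRNP -0.172 and fibroblast with T cell 0.138. Differentiation then gave 4 lower, and 2 lists had a smaller spread. Proliferation gave 0 and 15 by limma (701 higher at an adjusted p alone, 1966 at an unadjusted p of 0.05). With the arrays without signal kept, differentiation with columnar epithelium had -0.00209, basal with 3q26-q28 0.158 and SOX2 with TP63 0.00239, and the fits gave 5 lower for differentiation, 440 and 20 for proliferation, 13 lower for fibroblast and 31 higher for T cell.

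Over all alternatives, list pairs gave 519 further values, of which 463 kept their direction and side of the threshold, 17 lost it, 8 gained it and 31 reversed. Gene pairs gave 178 (162, 7, 7 and 2). No value exists for pairs whose genes or lists fell away under the strict filter, and the authors' log2 values carry no detection, so the small RNA count was not run with them. No paired analysis was possible because all arrays form 1 group with no matched tissue. Signal over background limits which genes were measured, and 87 list members were lost for this.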

Other observations

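Other list relations, chosen after their values were seen, came from 821 list pairs outside the preset ones, of which 110 passed in both sets (78 positive and 32 negative). Mesenchymal transition genes such as VIM rose with matrix metalloproteinases (r = 0.86 over 105 tumours and 0.86 block-centred, permutation p = 1e-05, the smallest the permutations can give, adjusted p = 0.000124, rho = 0.87, r = 0.86 without the 2 farthest tumours, positive in 8 of 8 blocks with at least 6 tumours). Macrophage genes such as C1QC rose with the measured immune checkpoint genes, without CD274, PDCD1 and PDCD1LG2 (r = 0.76, 0.82 block-centred, rho = 0.72, r = 0.75 without the 2 farthest tumours, 8 of 8 blocks). Genes of 3q26-q28 rose with NRF2 target genes (r = 0.47, 0.47 block-centred, rho = 0.42, r = 0.48 without the 2 farthest tumours, 8 of 8 blocks). Basal keratinocyte genes rose with hypoxia response genes (r = 0.63, 0.57 block-centred, 8 of 8 blocks) and fell with columnar epithelium genes (r = -0.49, -0.40 block-centred, 8 of 8 blocks). T-cell genes fell with glycolysis genes (r = -0.49, -0.42 block-centred, 5 of 8 blocks), and MHC class II with cholesterol synthesis genes (r = -0.32, -0.43 block-centred, adjusted p = 0.00636, 7 of 8 blocks).

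By chromosome band, 435 of 670 bands with at least 5 measured genes varied together more than random lists in both sets. In 3q26.33 the mean pairwise r was 0.34 over 11 genes (0.36 block-centred), led by NDUFB5, ACTL6A and DNAJC19. In 13q22.1 it was 0.20 over 8 genes (0.30 block-centred), led by the RNA exosome nuclease DIS3, MZT1 and PIBF1. In 6p24.2 TMEM14B, TMEM14C and PAK1IP1 led (0.35, 0.40 block-centred). Bands were chosen after their values were seen.

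Explanations were weighed for 3 patterns, with the tests of low signal and block offsets for the proliferation counts and of low signal for 11q13.3 chosen after seeing the result. No biological explanation named by the labels was tested, since they give 1 group, and those on cell mixture and position below rest on the expression values alone.

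The proliferation fit called 343 genes such as MCM2 and PCNA over all tumours and 18 without the 15 doubtful arrays. The minimum slope is per SD of a score that was scaled anew in each set. A smaller number of tumours alone is argued against, since 50 random subsets of 90 tumours gave 64 to 551 genes. Low signal on those arrays stays open, since the count of 18 is the pattern itself. Residuals on array signal and detection over all tumours left 7 higher and 24 lower genes, which does not exclude it. Centring within blocks left 204 genes over all tumours (101 higher and 103 lower), and 0 higher and 15 lower without the doubtful arrays. The fall thus remained with offsets between blocks removed, which argues against them as its only source. No random subsets were drawn from the centred values, and a part of such offsets in the 343 genes stays open.

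Genes of 11q13.3 such as CCND1 and FADD varied together, and low signal on some arrays is argued against, since without the doubtful arrays their mean pairwise r was 0.436 against 0.0504 at the 95th percentile of random lists. With the fibroblast, T-cell, basal keratinocyte and smooth muscle scores held constant, the mean pairwise r was 0.410 against 0.395 before. A cell mixture that these 4 scores track is thus argued against. None of them measures the share of tumour cells itself, so a mixture they miss stays open. Position on the chromosome stays open too. The 20 measured neighbours within 10 places had a median r with the list score 0.253 above that of 584 other 11q genes. The permutation p was 1e-04, the smallest the permutations can give. These permutations treat genes as independent, although genes of 435 of 670 bands varied together, so that p overstates the evidence. Neighbours such as MRPL21 (r = 0.51) and IGHMBP2 (r = 0.53) may share a gain of the region, which is a hypothesis, as copy number was not measured.

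NRF2 target genes such as AKR1C2 were lower where the T-cell score was higher (r = -0.274, 95% interval -0.411 to -0.114, n = 105). With 3 epithelial scores held constant r was -0.331 (-0.479 to -0.179), so these scores do not account for the relation. A smaller share of epithelial cells stays open, since none of the scores measures that share itself. The squamous differentiation score, 1 of them, had r = 0.043 with NRF2 target genes, so holding it constant could remove little. Low signal on some arrays stays open, since without the doubtful arrays r was -0.204 with an interval of -0.359 to -0.00987, and block-centred -0.180 with an interval that includes 0 (-0.334 to 0.0122). The first of these met the bound set beforehand against low signal (r under -0.2, interval below 0), but by less than its spread. Block-centred with the 3 epithelial scores held constant r was -0.265 (-0.477 to -0.0507), which lies beyond that bound by less than its spread too.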
